A study of Homo sapiens with 6 samples.

How the data were processed

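RRBS libraries of HepG2 cells were analysed from the processed files of the series: 3 lists of differentially methylated regions and a mapping summary of the 6 libraries. Per the labels' protocols, genomic DNA with a lambda DNA spike-in was cut with MspI, ligated to adapters with methylated cytosines and treated with bisulfite. The group of each library (control lentivirus or DNMT3A overexpression) and its replicate number were taken from the labels. Per the file headers, each list compares the overexpressing and the control library of the same number, so calls exist per pair and not per group. The genome build was hg38 per the submitters' processing notes. The aligner, the region caller, its version and its thresholds are not given in the sources used here, nor is the bisulfite conversion rate.

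Per the file headers, the authors gave for each region its mean methylation level in both libraries, a fraction from 0 to 1. The deposited counts are the number of CpG sites of each region, its length in bp, and the total and mapped reads of each library. The authors' lists also hold a signed difference of the levels and an area score, whose sign is that of the difference. The deposited difference equalled the overexpressing level minus the control level in every region within 1e-12. The mapping rate and the MspI cutting efficiency are percent values of the authors, and the definition of the latter is not stated. The lists do not say whether the CpG sites of both strands were counted separately. They give no reads per region, so no coverage minimum could be applied and a thinly covered region cannot be told from a well covered one. Because a region enters a list only when it was called, and both levels come from the reads used for the call, listed differences tend to be larger than those a fresh measurement would give.

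Regions of different lists were taken as shared when they overlapped by at least 1 bp, and chains of overlapping regions were merged into distinct regions. Where a pair had several regions in a merged region, its value is their mean weighted by CpG sites. Direction between lists was compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. All odds ratios given with Fisher's exact tests were computed after adding 0.5 to each count. At the 272 regions listed in all 3 pairs, levels of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on the logit scale with an offset of 0.01, without a replicate block, at an adjusted p under 0.05. The boundaries of such a region can differ between pairs, which adds to the spread between libraries. The limma step was tested on simulated levels of 272 regions for this comparison. It called 45.5% of 33 regions changed by 0.5 on the logit scale, 94.1% of 34 changed by 1 and 100% of 33 changed by 2, and 1 of 172 unchanged regions.

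The replicate numbers were checked for pairing before the fits were compared. Deviations from the group means correlated between same-numbered libraries at 0.393, 0.295 and 0.313 across the 272 regions, while libraries of different numbers correlated at -0.131 to -0.201. Such deviations cancel out within a group, so positive same-numbered correlations force negative ones between different numbers. The contrast is therefore no separate evidence of pairing. Over the 51 regions with identical boundaries in all pairs the same-numbered correlations were 0.307, 0.350 and 0.341. Every same-numbered correlation was above 0.1 and the authors compared the same numbers, so the numbers were taken to pair the libraries. The fit without a block had been planned and stayed the main one, with the blocked fit as an alternative. Regions were selected within pairs and given boundaries pair by pair, which could itself raise these correlations.

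Positions were compared with the RefSeq gene table of GRCh38.p14, the same build, using 20056 protein-coding and 18330 long noncoding RNA genes. That table gives the extent of genes but not strand, exons or CpG islands. The planned classes of promoter, exon, intron and CpG island were therefore replaced by gene body (inside a gene and over 1 kb from its ends), gene end (within 1 kb of either end of a gene) and intergenic, with a class of at least 10 CpG sites per 100 bp added after seeing the data. Gains and losses were compared in each class with Fisher's exact test, adjusted over the 4 classes. A region was assigned to every gene within 1 kb, so overlapping genes share regions and do not count as independent.

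The 14 gene lists were fixed before the data were examined: DNA methylation machinery, HOX genes, other developmental transcription factors, hepatocyte function, lipid and cholesterol metabolism, genes methylated in cancers, imprinted genes, clustered protocadherins, zinc finger genes with ZNF-type symbols, WNT pathway, germline genes, ion channels and neuronal genes, matrix genes, and markers of other cell types. A family entry takes symbols that begin with its prefix, followed by at most 1 letter and a digit, so a divergent transcript such as FOXF2-DT counts. Genes with gains only were set against genes with losses only by Fisher's exact test, adjusted over the 14 lists. The regions named were also set by rule beforehand. They are the 10 largest gains and 10 largest losses listed in all 3 pairs (filled from 2 pairs where fewer existed), the 2 largest gains and losses of each pair, up to 4 members per list and direction called in at least 2 pairs, and the DNMT and TET genes. A region that this rule takes is not reported here.

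Library statistics were compared with exact two-sided permutation tests. Intervals of shares are exact (Clopper-Pearson) 95% intervals and cover counting only. Alternatives were stricter minimum differences of 0.2 and 0.3, at least 10 CpG sites, autosomes only, an overlap of 50%, a gap of up to 500 bp, other scales and offsets for limma, the replicate block, a single region per gene, gene ends only, and leaving out each library or pair. Added after seeing the data were recurrence by direction, also at equal list lengths, the CpG-dense class, a window of 2 kb, regions in at least 2 pairs for the comparison of positions, and shared regions on autosomes only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.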

Results

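DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in HepG2 cells, an established human hepatocellular carcinoma line. RRBS cuts genomic DNA with MspI, which enriches CpG-rich fragments, and bisulfite then converts unmethylated cytosines, so that methylated ones can be counted. Cells infected with a control lentivirus were compared with cells infected with a lentivirus that overexpresses DNMT3A, a de novo DNA methyltransferase. Each group had 3 libraries, numbered 1 to 3, and the deposited lists of differentially methylated regions set each overexpressing library against the control library of the same number. The labels do not say that the 3 libraries of a group came from separate cultures. The p-values of limma and of the permutation and sign-flip tests therefore measure only the spread between these libraries, which may be technical. Those of Fisher's exact tests count regions, overlaps or genes and hold no spread between libraries. They treat neighbouring regions and overlapping genes as independent, which these are not.

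Total reads per library ranged from 33512387 to 39245256, and mapped reads from 25764323 to 29924507. Mapped reads averaged 27.9 M ± 2.08 (mega-reads; SD, n = 3) in the overexpressing libraries and 27.8 M ± 1.29 (SD, n = 3) in the controls (exact two-sided permutation test, p = 1). Total reads averaged 36.4 M ± 2.87 and 36.5 M ± 1.64 (exact permutation p = 1). The mapping rate was 76.6% ± 0.317 in overexpressing and 76.1% ± 0.121 in control libraries, and the MspI cutting efficiency 99.63% ± 0.0173 and 99.66% ± 0.00577. For both percentages all 3 overexpressing libraries lay on the same side of all 3 controls, at the smallest p that 3 libraries against 3 allow (exact permutation p = 0.1, adjusted p = 0.2 over 4 statistics). The lists give no read depth per region, so the depth behind each regional level is unknown and no interval is given for it.

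The first question was how many regions differed in methylation when DNMT3A was overexpressed, and in which direction. Regions with higher methylation in the DNMT3A-overexpressing library made up most of every list. Pair 1 listed 1217 regions higher and 266 lower, pair 2 listed 1171 higher and 262 lower, and pair 3 listed 1158 higher and 270 lower. The higher regions were 82.1% (95% exact binomial interval 80.0 to 84.0), 81.7% (79.6 to 83.7) and 81.1% (79.0 to 83.1) of the 3 lists, a mean of 81.6% ± 0.492 (SD, n = 3). These intervals cover the counting of regions only.

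Regions that were higher started from low levels and ended at intermediate ones. Their median level was 0.184, 0.192 and 0.209 in control libraries 1, 2 and 3, against 0.505, 0.508 and 0.523 in the overexpressing libraries, with median differences of 0.264, 0.266 and 0.265. Regions that were lower went from medians of 0.587, 0.596 and 0.547 in the controls to 0.260, 0.279 and 0.220, with median differences of -0.277, -0.269 and -0.267. Over all listed regions the mean difference was 0.171 ± 0.00333 (SD, n = 3 pairs), positive in 3 of 3 pairs, and the exact two-sided sign-flip p of 0.25 is the smallest that 3 pairs can give. Listed regions spanned 51 to 5025 bp and held 4 to 153 CpG sites. The lists hold called regions only, so these values describe the calls and not the methylation of the whole genome.

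**Figure D1:**
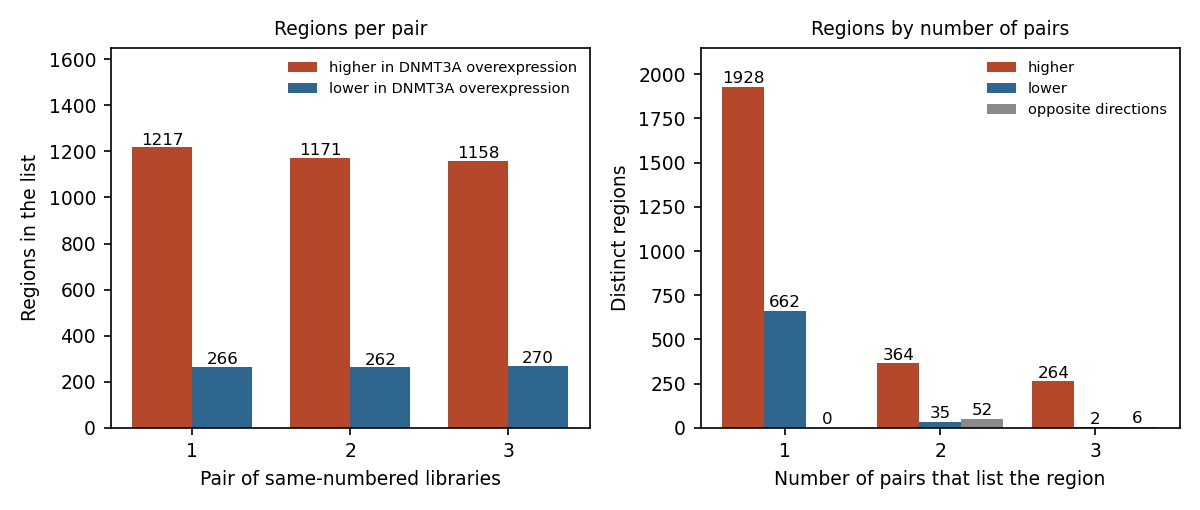
Left, number of listed regions (y axis) that were higher or lower in the DNMT3A-overexpressing library, for each pair of same-numbered libraries (x axis). Right, number of distinct regions by how many pairs listed them, split into higher, lower and opposite directions. Higher regions outnumber lower ones in each pair, 1217 against 266 in pair 1, and 264 regions were higher but 2 lower in all 3 pairs.

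Whether a region called in 1 pair was called again in another was asked next, since this is the replicate check that the lists allow. Gains of methylation recurred and the few recurrent losses included the DNMT3A gene itself. Merging overlapping regions gave 3313 distinct regions, of which 272 were listed in all 3 pairs. Of these, 264 were higher in every pair, 2 were lower in every pair, in DNMT3A and in GRIN2D, and 6 went in opposite directions. A further 364 regions were higher and 35 lower in exactly 2 pairs, with 52 in opposite directions, while 1928 higher and 662 lower regions appeared in 1 pair only.

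Overlapping regions had the same direction in 95.4% of 452 overlaps between pairs 1 and 2, against 89.0% expected from the totals of each direction (Fisher's exact test, odds ratio 57.7, adjusted p = 1.32e-15). The shares were 94.6% of 443 overlaps against 89.8% between pairs 1 and 3 (odds ratio 32.6, adjusted p = 5.2e-11), and 95.4% of 413 against 89.2% between pairs 2 and 3 (odds ratio 69.2, adjusted p = 1.54e-14). In a comparison chosen after seeing the data, 31.3% to 35.2% of the gains of a list met a gain of another list, whereas 1.85% to 5.34% of its losses met that same list of gains (6 Fisher's exact tests, largest adjusted p = 1.17e-21). Likewise 4.44% to 6.11% of losses met a loss of another list, against 0.427% to 1.21% of gains meeting that list of losses (largest adjusted p = 0.000511). The lists of losses are much shorter than those of gains, so shares meeting a gain list and shares meeting a loss list are not on an equal footing. Direction is also bound to the starting level, with median control levels of 0.184 to 0.209 at gains and 0.547 to 0.596 at losses. A region with a low level in every control can be called higher but hardly lower. Agreement in direction could thus follow from stable control levels alone, which was not tested.

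**Figure D2:**
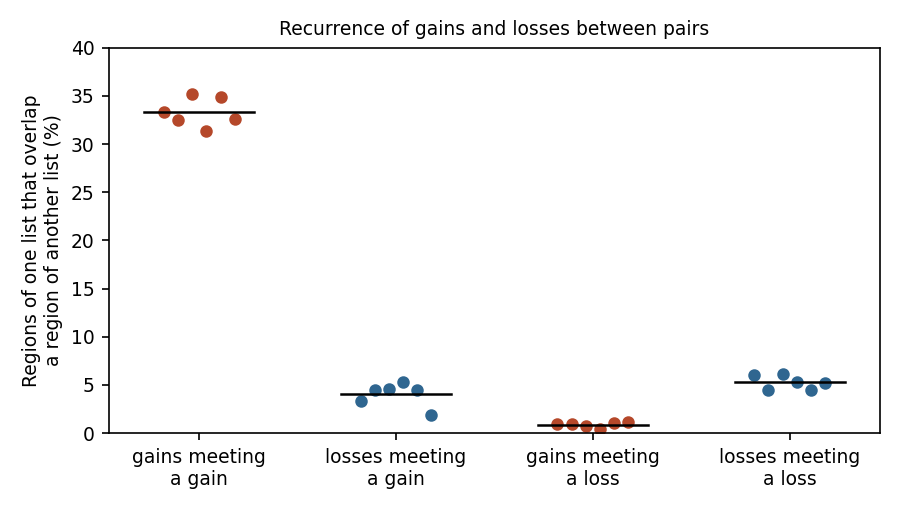
Share of the regions of a list (y axis, percent) that overlap a region of another pair's list by at least 1 bp, for gains and losses against lists of gains and of losses (x axis). Each point is 1 of 6 ordered comparisons of lists and the bar is their mean: 33.3% of gains and 4.02% of losses met a gain, and 0.888% of gains and 5.27% of losses met a loss.

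At the 264 shared gains the median level was 0.148 in the controls (interquartile range 0.0861 to 0.251) and 0.459 in the overexpressing libraries (0.341 to 0.588), with a median difference of 0.280 (0.227 to 0.327). The median SD was 0.0216 between control libraries and 0.0338 between overexpressing libraries. At 260 of the 264 regions (98.5%) every overexpressing library lay above every control. All 264 were chosen for being higher in each pair, and among orders of 6 values that meet this condition chance gives 40%. Each also had to be called in each pair, and the median difference is large against these SDs. Selection alone can thus give a share well above 40%, so the 98.5% does not measure an excess over chance. With limma on the logit scale, 261 of the 272 regions listed in all 3 pairs rose and 2 fell at an adjusted p under 0.05. These regions were chosen because each pair called them, so the test is not independent evidence of a change.

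The regions that did not pass were the 6 in opposite directions and 3 gains. The gains were in PLAUR, the urokinase receptor gene (difference 0.212 ± 0.0739, SD, n = 3), in TTYH3 (0.257 ± 0.0323) and in LINC02913 (0.210 ± 0.0620), with limma adjusted p = 0.0566, 0.0682 and 0.0556. With the replicate number as a block they did pass, at adjusted p = 0.00111, 0.000196 and 0.000247. The 6 regions in opposite directions, in or near RXRG, KCTD12, ARRDC2, PRELID3B and HOXA3 and at chromosome 20: 30585393-30585628, which has no gene within 1 kb, varied widely within groups. Their median SD was 0.167 between controls and 0.162 between overexpressing libraries.

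Among the largest shared gains were regions in JARID2, KCNQ1 and ECE1. All coordinates are those of the files, on hg38. In JARID2, which encodes an accessory subunit of Polycomb repressive complex 2, the region at chromosome 6: 15505114-15505255, inside the gene body, rose from 0.149 ± 0.0406 to 0.615 ± 0.0386 (SD, n = 3 per group; limma adjusted p = 1.88e-05). In KCNQ1, a voltage-gated potassium channel gene within an imprinted domain, the region at chromosome 11: 2533949-2534018 rose from 0.213 ± 0.0456 to 0.678 ± 0.0607 (limma adjusted p = 3.48e-05). The region in ECE1, the gene of an endothelin-converting enzyme, at chromosome 1: 21262675-21263113, inside that gene and within 1 kb of an end of the noncoding gene LOC124903872, rose from 0.183 ± 0.00688 to 0.625 ± 0.00691 (limma adjusted p = 9.38e-06).

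A further 6 of the 10 largest gains lay inside gene bodies, more than 1 kb from an end. They were in PITPNM2 (chromosome 12: 123075837-123075977, from 0.230 to 0.683), in FOXF2-DT, the long noncoding RNA gene beside FOXF2 (chromosome 6: 1326598-1326681, from 0.192 to 0.646), and in SPOCK2, a matrix proteoglycan gene (chromosome 10: 72086566-72086718, from 0.106 to 0.558). The remaining regions were in BICRA, which encodes a SWI/SNF subunit (chromosome 19: 47663111-47663245, from 0.242 to 0.676), in NXN (chromosome 17: 951729-951885, from 0.272 to 0.705) and in PGAP6 (chromosome 16: 383504-384082, from 0.334 to 0.765). The SD between the 3 pairs' differences ranged over these regions from 0.0258 in BICRA to 0.123 in PITPNM2, and the limma adjusted p from 1.47e-05 in FOXF2-DT to 0.00026 in PGAP6. At PGAP6, control library 3 stood at 0.474, above 0.256 and 0.274 in control libraries 1 and 2.

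Losses shared by all 3 pairs were 2. In DNMT3A, the overexpressed gene, the region at chromosome 2: 25247939-25248133 fell from 0.892 ± 0.00325 to 0.629 ± 0.0212, a difference of -0.263 ± 0.0244 (SD, n = 3; limma adjusted p = 1.41e-05). It lies inside the gene body, and its place among exons and introns was not analysed here, nor was the vector's sequence, so reads of the endogenous gene and of an introduced coding sequence cannot be separated. In GRIN2D, an NMDA receptor subunit gene, the gene-body region at chromosome 19: 48398668-48398870 fell from 0.576 ± 0.00577 to 0.335 ± 0.0524 (limma adjusted p = 0.000229).

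The next 8 losses by size were listed in 2 pairs and so have no test across the 6 libraries. The largest, at chromosome 11: 116580237-116580484, lies 167689 bp from BUD13, the nearest protein-coding gene, and differed by -0.307 in pair 2 and -0.667 in pair 3. Within 1 kb of a gene end were a region inside MELTF near an end of the noncoding gene MELTF-AS1 (chromosome 3: 197003488-197003718, mean difference -0.430), and regions of LOC124904792 (chromosome 19: 53197524-53197731, -0.360), CCDC71L (chromosome 7: 106660583-106660836, -0.324), MAMLD1 (chromosome X: 150361970-150362066, -0.310) and ZBTB14 (chromosome 18: 5296848-5297028, -0.297). The others were in the noncoding gene LOC105370982 (chromosome 15: 93218174-93218425, -0.421) and at chromosome 8: 67946097-67946163, 5883 bp from PREX2 (-0.376).

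**Figure D3:**
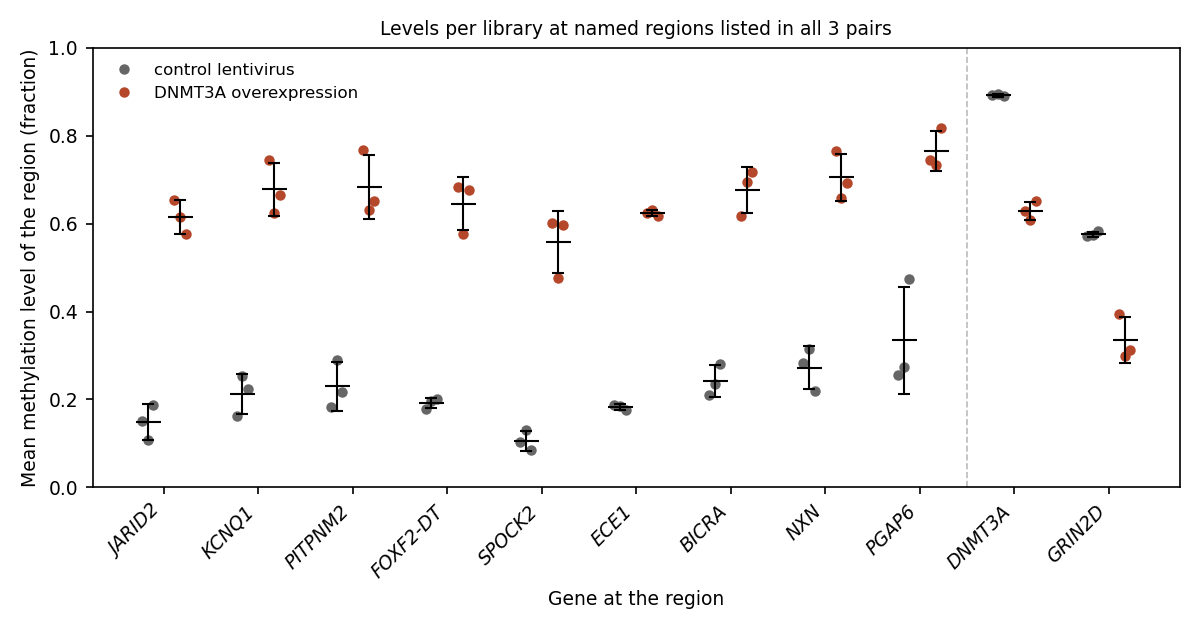
Mean methylation level (y axis, fraction) in each library at the largest gains described here and the 2 losses listed in all 3 pairs, by gene (x axis); points are libraries, bars the mean and whiskers the SD of 3 libraries. Overexpressing libraries lie above controls at the gains, as at ECE1 with means of 0.625 and 0.183, and below them at DNMT3A and GRIN2D, to the right of the dashed line.

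The largest differences of single pairs were mostly not repeated. In pair 1, SLC39A11 (chromosome 17: 73061084-73061217) stood at 0.122 in the control and 0.861 in the overexpressing library, and a region shared by MYRIP and EIF1B-AS1 (chromosome 3: 40245505-40245573) at 0.0351 and 0.753. In pair 2, a region of the noncoding gene LOC101928283 (chromosome 7: 125204936-125205037) stood at 0.967 and 0.0223, and PER1, a circadian clock gene (chromosome 17: 8152618-8152708, 214 bp outside the gene), at 0.969 and 0.0356. In pair 3, RBMS1 (chromosome 2: 160408630-160408815) stood at 0.0220 and 0.747, ADAMTS2 (chromosome 5: 179209670-179209918) at 0.172 and 0.888, the region of GATAD1 and ERVW-1 (chromosome 7: 92469084-92469148) at 0.820 and 0.0410, and CCDC88C (chromosome 14: 91414881-91414982) at 0.920 and 0.223.

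Of the 4 single-pair extremes without a gene within 1 kb, chromosome 11: 126185604-126185722, nearest to RPUSD4, was higher in 2 pairs and stood at 0.0348 and 0.823 in pair 2. Another, at chromosome 1: 226100649-226100770, nearest to H3-3A, stood at 0.889 and 0.0248 in pair 1 and went the other way in a second pair. The remaining ones, at chromosome 3: 64348599-64348667 (0.804 and 0.0346 in pair 1) and chromosome 15: 63080176-63080278 (0.0290 and 0.736 in pair 2), were listed once, as were all 8 with a gene. These 12 regions held 4 to 10 CpG sites each.

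Position relative to genes was compared between gains and losses within each list, since the regions that RRBS covered without a call are unknown. Gains lay inside gene bodies more often than losses, and losses near gene ends more often than gains. In pairs 1, 2 and 3, 58.2%, 59.3% and 58.0% of gains lay inside a gene and over 1 kb from its ends, against 41.0%, 42.4% and 35.9% of losses (Fisher's exact test, odds ratios 2.00, 1.98 and 2.46, adjusted p = 1.68e-06, 1.78e-06 and 2.24e-10). Within 1 kb of a gene end lay 20.9%, 20.8% and 23.5% of gains against 32.0%, 35.9% and 34.1% of losses (adjusted p = 0.000294, 1.78e-06 and 0.000624). With a window of 2 kb, chosen after seeing the data, the gene-end difference of pair 1 did not pass (adjusted p = 0.0539).

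Intergenic regions were a larger share of losses in pair 1 (27.1% against 21.0% of gains, adjusted p = 0.0449) and pair 3 (30% against 18.5%, adjusted p = 0.000111), but pair 2 did not pass (21.8% against 19.98%, adjusted p = 0.552). Regions with at least 10 CpG sites per 100 bp, a class added after seeing the data, were 57.9% of gains and 65.3% of losses in pair 2 (adjusted p = 0.0414) and did not pass in pairs 1 and 3 (adjusted p = 0.132 and 0.0861). Among regions listed in all 3 pairs no class passed, with 2 losses to compare.

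Over regions listed in at least 2 pairs in the same direction, also chosen after seeing the data, 62.2% of 37 losses lay near a gene end against 19.3% of 628 gains (adjusted p = 1.76e-07), and 29.7% against 66.4% inside a gene body (adjusted p = 1.61e-05). Of these losses 89.2% were CpG-dense, against 51.8% of gains (adjusted p = 8.28e-06). Without pair 2, which leaves 12 losses, these differences did not pass: 50% of losses against 19.6% of gains near gene ends (adjusted p = 0.0755), 41.7% against 66.9% inside gene bodies (0.155) and 83.3% against 51.1% CpG-dense (0.0755). They passed without pair 1, with 14 losses (adjusted p = 0.00956, 0.0132 and 0.0161), and without pair 3, with 16 losses (adjusted p = 0.000206, 0.0364 and 0.000135).

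**Figure D4:**
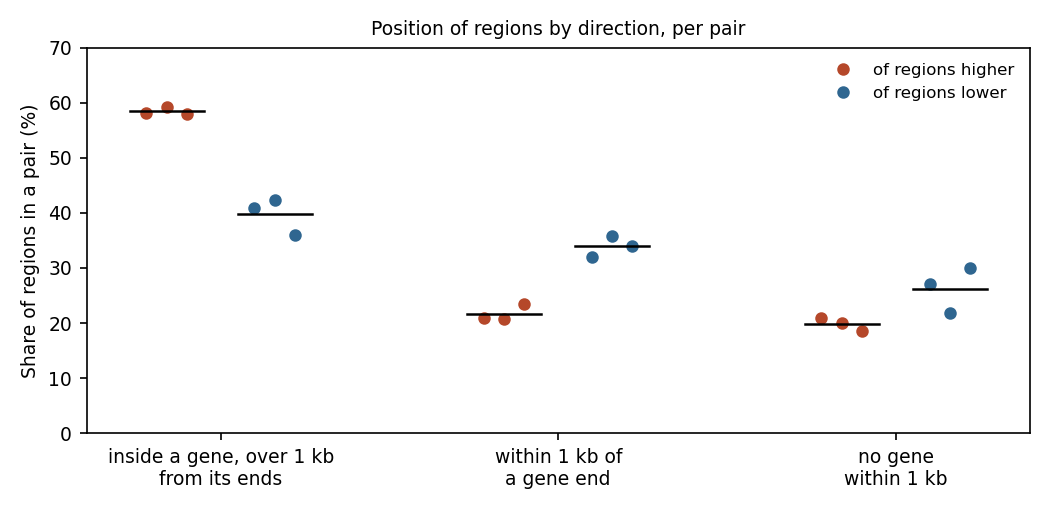
Share of gains and of losses (y axis, percent) by position relative to annotated genes (x axis), with a point per pair and a bar at the mean of 3 pairs. Gene-body shares are 58.0% to 59.3% of gains and 35.9% to 42.4% of losses, and gene-end shares 20.8% to 23.5% and 32.0% to 35.9%.

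Genes of the DNA methylation machinery were examined by name. All 4 regions listed in DNMT3A were lower, those at the shared position and a second one in pair 3 at chromosome 2: 25244126-25244178 (0.934 in the control and 0.820 in the overexpressing library). All 5 regions listed in TET3, which encodes a 5-methylcytosine dioxygenase, were higher, and the shared one at chromosome 2: 74002468-74002680 rose from 0.0908 ± 0.0331 to 0.226 ± 0.0337 (SD, n = 3; limma adjusted p = 0.00199). ZBTB4, a methyl-CpG binding zinc finger gene (chromosome 17: 7477876-7477973), was higher in 2 pairs, by a mean of 0.290. No region was listed in DNMT1, DNMT3B, DNMT3L, TET1 or TET2, which shows only that none was called there.

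Across 14 gene lists fixed before the data were examined, no list passed for a difference in direction from the other genes with a region in at least 2 pairs. These were 622 genes with gains only, 62 with losses only and 12 with both, and Fisher's exact test gave adjusted p = 0.174 for zinc finger genes and 1 for the other 13 lists. With so few genes with losses only, lists of these sizes could hardly pass for an excess of gains. The test could therefore detect mainly an excess of losses, and a list richer in gains is not excluded. Where a gene had several regions, the differences given are the mean over pairs of its largest one, which need not be the same region in each pair. The SD of such a mean can then also hold differences between regions. A gene counted as higher only, or lower only, by calls in at least 2 pairs, so a single pair may still have listed a region of it in the opposite direction. Among named genes this was so, with a lower region in 1 pair, for FOXF2-DT (-0.174), MNX1 (-0.345), KCNQ1 (-0.241), ONECUT1 (-0.198), ZNF469 (-0.471), HOXA5 (-0.266), ADAMTS2 (-0.529) and ECE1 (-0.155). A higher region in 1 pair was listed for NKX6-1 (0.364), NKX2-2 (0.152), GRIN2D (0.315), GRB10 (0.230), MELTF (0.221), CCDC71L (0.664) and ZBTB14 (0.246).

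Of the list of developmental transcription factors other than HOX, 19 genes were higher only, 3 lower only and 1 both. At MEIS2, a homeobox gene, the shared region at chromosome 15: 37097086-37097279 rose from 0.116 ± 0.0328 to 0.530 ± 0.0627 (SD, n = 3; limma adjusted p = 2.7e-05), and at the forkhead gene FOXB1, chromosome 15: 60004194-60004472, from 0.257 ± 0.170 to 0.608 ± 0.0764 (limma adjusted p = 0.0153). MNX1 was higher by a mean of 0.400 ± 0.195. GATA2, NKX6-1, RAX and NKX2-2 were listed lower in 2 pairs, by means of -0.317 ± 0.232 (SD, n = 2), -0.265, -0.243 and -0.240. The 2 losses of GATA2 lay at different places, so neither recurred. GATA2 also had a gain in all 3 pairs (chromosome 3: 128490303-128490688, limma adjusted p = 3.53e-05). The losses spread over chromosome 18: 59267823-59273535 in RAX and chromosome 20: 21513964-21518317 in NKX2-2, so these means may also join different regions. All 8 regions of this list that were listed in all 3 pairs rose in limma, and 8 also did when adjusted over the list alone. This is near the share of all regions, of which 261 of 272 rose. Of the HOX genes, HOXA5 and HOXA7 were higher in 2 pairs, by means of 0.396 ± 0.0110 and 0.380 ± 0.189 (SD, n = 2). HOXA3 had both gains (0.443) and losses (-0.208). The 2 gains of HOXA7, and the 2 losses of HOXA3, lay at different places. The region listed in all 3 pairs that was assigned to both HOXA3 and HOXA5 was lower in pair 1 (-0.266) and higher in pairs 2 and 3 (0.389 and 0.404), and did not pass.

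Ion channel and neuronal genes were 16 higher only and 1 lower only, the latter GRIN2D. Apart from KCNQ1, the leading members were GRID1 (mean difference 0.525 ± 0.238 over 2 pairs), the T-type calcium channel gene CACNA1H (0.479 ± 0.135 over 3 pairs) and the ephrin receptor gene EPHA2 (0.430 ± 0.0268). In limma 13 of the 14 regions of this list rose and 1 fell, with the same counts when adjusted over the list alone. Of all 272 tested regions 261 rose and 2 fell, so these counts lie near the share of all regions. Genes of the extracellular matrix were 11 higher and 1 lower: ADAMTS2 (0.616), ADAMTSL2 (0.450) and a region shared by ADAMTSL4 and ADAMTSL4-AS2 (0.401) led the gains, and FBN2 was lower (-0.178). The ADAMTS2 mean joins different regions, since that of pair 3 (0.716, chromosome 5: 179209670-179209918) was listed in no other pair. Another region of ADAMTS2, at chromosome 5: 179171286-179171494, was lower in pair 3 (-0.529).

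Zinc finger genes had more losses than the other genes in pair 1. There, 11 were higher only and 12 lower only, against 907 and 208 for all genes (odds ratio 0.202, adjusted p = 0.00362). Pairs 2 and 3 each had 9 higher and 7 lower and did not pass (adjusted p = 0.150 and 0.249), although their odds ratios of 0.297 and 0.284 also lay on the side of losses. Pair 1 did not pass when only regions near gene ends were kept (odds ratio 0.182, adjusted p = 0.0538). Whether the pairs differed from each other was not tested. At a minimum difference of 0.2, pair 3 did pass, with 4 higher and 7 lower (adjusted p = 0.01004), as did pair 1 (adjusted p = 0.00949), but not pair 2 (adjusted p = 0.0971). Over genes called in any pair, 19 were higher only and 21 lower only (adjusted p = 0.000231). In at least 2 pairs, 7 were higher, among them ZFPM1 (0.344), ZNF469 (0.336), ZNF236-DT (0.279) and ZNF860 (0.230), and 4 were lower: ZNF844 (-0.249), ZNF558 (-0.246), ZNF536 (-0.219) and ZNF879 (-0.164), an odds ratio of 0.158 that did not pass (adjusted p = 0.174). Without pair 3, with 4 higher and 4 lower, the difference in direction passed (odds ratio 0.0502, adjusted p = 0.00603). It did not pass without pair 1 (4 higher and 0 lower) or pair 2 (3 higher and 0 lower), each at an adjusted p of 1. With 0 lower these counts lay on the side of gains. Their odds ratios of 0.639 and 0.358 fell under 1 only through the constant added to each count. The losses in at least 2 pairs thus came from pairs 1 and 2.

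Of the 97 members of the hepatocyte function list in the reference, 3 were higher in at least 2 pairs and none lower. Membership is that of the list as fixed beforehand, and not every member is particular to hepatocytes. These were ASGR2, an asialoglycoprotein receptor gene (0.248), ONECUT1, a liver transcription factor gene (0.241), and EPCAM (0.143). Among lipid and cholesterol genes the desaturase gene FADS2 was higher (0.119). Of genes known to be methylated in cancers, SEPTIN9 (0.402), SOCS3 (0.304 ± 0.0381) and DAPK1 (0.203) were higher and the DNA repair gene MGMT was lower (-0.212). The SOCS3 region, at chromosome 17: 78359518-78359594, rose in limma (adjusted p = 2.03e-05).

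Imprinted genes went both ways. KCNQ1 (0.465) and TRAPPC9 (0.372) were higher, GRB10 was listed lower in 2 pairs (-0.0298 in pair 1 and -0.283 in pair 2) and also higher in pair 1 (0.230), and GNAS had both gains (0.182 ± 0.0477, SD, n = 2, chromosome 20: 58890516-58890713) and losses (-0.257 ± 0.159, chromosome 20: 58888736-58888984). Of the WNT pathway, the co-receptor gene LRP5 (0.339), TCF7 (0.256) and FZD4 (0.154) were higher. The germline gene TDRD9 was higher in 2 pairs (0.369), and of the markers of blood, endothelium and fibroblasts THY1 was higher (0.186 ± 0.0338; limma adjusted p = 0.00113). No clustered protocadherin was listed in 2 pairs. In pair 2 all 20 members with a region, PCDHGA1 among them, shared a single region inside these nested genes (chromosome 5: 141477625-141477750, 0.425 in the control and 0.648 in the overexpressing library), and the list did not pass there (adjusted p = 0.150).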

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

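The excess of gains and the match in direction between overlapping regions held under all alternatives run. A minimum difference of 0.3 left 576, 545 and 544 regions in pairs 1, 2 and 3, with 78.8% higher in pair 1 and 78.5% in pair 3, and a minimum of 10 CpG sites left 919, 887 and 896, as stricter filters must leave fewer. Of regions listed in all 3 pairs, those in opposite directions numbered 3 with an overlap of 50%, 13 with a gap of up to 500 bp and 3 at a difference of 0.2, which also left 1 loss. Leaving out each pair in turn, regions listed in both others numbered 365 to 403 higher, 12 to 16 lower and 19 to 23 opposite, since 2 lists are easier to share than 3. With limma, leaving out libraries or pairs gave 258 to 264 regions higher and 2 to 3 lower. The replicate block gave 264 higher and 2 lower, adding PLAUR, TTYH3 and LINC02913 and changing no other call. Regions called in every pair, and the largest of them above all, are likely to hold through that selection alone. The 10 largest gains and 2 losses in all 3 pairs kept call and direction in all 144 region-by-alternative combinations (highest limma adjusted p = 0.00983). Of 22 other tested regions in genes named from the lists 21 did so, up to 0.0453 at FOXB1, while the region of HOXA3 and HOXA5 passed without pair 1 (limma adjusted p = 0.0169) or without control 1 (0.0293). The intergenic difference passed in 1 pair with a single region per gene, and the CpG-dense difference, added after seeing the data, in 0 pairs at a difference of 0.2 and in 2 with a single region per gene; the cause was not tested. Gene lists passing numbered 0 in pair 1 with gene ends only (fewer genes tested), 1 in pair 3 at a difference of 0.2 (zinc finger genes), and 1 over genes called in any pair. Over genes in at least 2 pairs, leaving out a pair gave 0 to 1 lists, the latter without pair 3. The differences in reads between groups had no fixed sign, in mega-reads (M): without single libraries they ranged from -1.54 to 1.33 M total reads and from -0.932 to 1.15 M mapped reads. Leave-out differences that changed sign were 0.818 and 1.33 M total reads (without control 1 and overexpressing library 3), and -0.932, -0.351 and -0.209 M mapped reads (without overexpressing library 1 and controls 2 and 3). Depth per region is unknown, so no limit from coverage can be given.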

Other observations

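Several genes carried separate gains spread along their length. CACNA1H, a T-type calcium channel gene, had 10 separate recurrent gains between 1158440 and 1194172 on chromosome 16, 5 of them in all 3 pairs. Its mean differences ranged from 0.130 to 0.556. The 5 regions in all 3 pairs passed in limma, with adjusted p from 1.41e-05 to 0.00202. GNG7, a G protein gamma subunit gene, had 7 on chromosome 19 between 2513015 and 2602743, 6 of them in all 3 pairs, with differences from 0.212 to 0.360. BCL11B, a zinc finger transcription factor gene, had 5, and BCOR, NFIX, PRDM16, TRAPPC9, SEPTIN9 and PTPRN2 had 4 each. BCOR also had a region that was lower in pairs 1 and 2 (-0.166 and -0.160). These genes were chosen after their values were seen, and long genes with many CpG-rich fragments have more chances to be listed.

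Some gains covered long stretches. A merged region of 1440 bp lay inside IGF1R, the insulin-like growth factor receptor gene, and at an end of the noncoding gene LOC124903561 (chromosome 15: 98851112-98852551). With calls of 1302 to 1410 bp in the 3 pairs, it rose from 0.0375 ± 0.00401 to 0.223 ± 0.0339 (SD, n = 3, limma adjusted p = 1.41e-05). The longest listed region, of 5025 bp at chromosome 17: 17442405-17447429, was higher by 0.332 in pair 1 and 0.5001 in pair 2, but held only 14 CpG sites. PIEZO1, a mechanosensitive channel gene, had a region of 1519 bp in pairs 1 and 2 (chromosome 16: 88759348-88760866). Pair 3 listed no region of that length there, only a shorter part of it. Over the merged region, levels rose from 0.121 ± 0.00636 to 0.426 ± 0.0383 (SD, n = 3, limma adjusted p = 1.41e-05).

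Explanations were weighed for 3 patterns; the tests of noise, of list length, of call strength and level at equal list length, and of the introduced sequence were chosen after the results were seen. The first pattern is the recurrence of gains. Incomplete bisulfite conversion in the overexpressing libraries would have to leave a share of 0.355 of cytosines unconverted to give the median shared gain. At a rate equal over all regions, it would raise every region to at least that level. The lowest listed levels in these libraries were 0.00887, 0.0131 and 0.0102, and 32.3% to 33.7% of their listed regions lay below 0.355. This argues against a failure of that rate in all regions. A failure confined to some regions was not tested and stays open. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many regions past the limma threshold, the real one with 263, and the highest other had 0, also among the splits that part every pair (4 with the real one); the regions were selected in the real grouping, which itself sets the other splits low, and with 10 splits the share cannot go under 0.05. A gain of methylation through DNMT3A overexpression may be put forward only as a hypothesis, on regions selected for the difference and on libraries not stated to be separate cultures.

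The second pattern is that losses seldom recurred: 9.77% of losses met a loss of another pair (95% exact interval 7.80 to 12.05), whereas 44.3%, 44.0% and 44.0% of gains in pairs 1, 2 and 3 met a gain. A shared loss counts once from each list that holds it, so these counts are not independent and the interval is too narrow. The intervals of the odds ratios below share this limit. The lists of losses are shorter, and gains drawn at random to the number of losses in each pair met a gain in 13.9% of cases (median of 100 draws, range 10.9 to 17.9), so list length as the whole cause and a lower reproducibility of losses cannot be told apart. At equal length the odds ratio of recurrence, gains against losses, had a median of 1.49 (median interval 1.10 to 2.03) within pairs, of 1.54 (1.11 to 2.13) when also matched on area score and CpG sites, and of 1.52 (1.11 to 2.08) when matched on mean level. These intervals lay above 1 in 77, 78 and 77 of the 100 draws, so the gap left at equal length is itself not clear, and weaker calls and the position on the methylation scale stay open. Of the 87 regions listed in exactly 2 pairs with at least 1 loss, 35 were lower in both (40.2%, exact interval 29.9 to 51.3) where directions at random with equal odds give 33.3%, so losses that are library noise and real losses cannot be told apart either.

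The third pattern is the shared loss in DNMT3A itself. A candidate explanation is reads of the introduced coding sequence, which would carry its own methylation and map to the same exons, and it needs every listed region of the gene to be lower and to lie in a coding exon. Of the 4 regions listed in DNMT3A, 0 were higher in the overexpressing library, but 3 of them are the shared loss itself and 1 a region of pair 3 alone, so this count does not decide on reads of the introduced coding sequence. Exon positions and the vector sequence were not used here, so such reads and a loss at the endogenous gene cannot be told apart. A real loss of methylation in the gene body stays open as an untested biological explanation.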
